A study of Homo sapiens with 15 samples.

How the data were processed

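RNA was measured in 15 libraries of UMB1949 cells, 3 in each of 5 groups: untreated, rapamycin 0.05 µM, rapamycin 1 µM, imatinib 1 µM and imatinib 10 µM. Groups and replicate numbers came from the sample labels. Per the submitters' protocol notes, RNA was isolated with RNeasy columns and libraries were made with a TruSeq RNA kit. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20, quantified with kallisto 0.44.0 against GRCh38.p13 and tested with sleuth.

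The deposited gene table held estimated counts per gene, which the authors made from kallisto output and which were whole numbers in every cell. It had 35882 genes, of which 12147 were at 0 in all 15 libraries. Of its 28 columns, 15 belonged to samples of the series. The other 13 belonged to no sample described in the series and were not used. The deposited transcript files held estimated counts per transcript with decimals, with the effective transcript length and TPM that the authors' quantification gave. Library totals of both sources differed by at most 218 counts. A second file per sample repeated the first with more decimals and was not used. The annotation release of the gene table was not stated in the sources used here. By symbol, 27064 genes matched GENCODE 44, 741 more matched through an older symbol and 8077 did not match. Gene types and positions are from GENCODE 44 on GRCh38.

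Differential expression was computed on the gene table with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter with the 5 groups as its design, which left 14186 genes. Library sizes were scaled by trimmed mean of M values. A single model held all 15 libraries, with robust quasi-likelihood dispersions and the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method within each comparison, at a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM, counts scaled to a common library total, use the scaled library sizes, and levels are means ± SD over 3 libraries. Sleuth was not rerun, because bootstrap estimates were not used here. No molecular identifiers mark the reads, so the floor covers counting error only. Standard errors of log2 fold changes also take in the spread between libraries. An interval on a share of genes is binomial, takes genes as independent and covers neither. A floor of 3 counts lay between 0.100 and 0.172 CPM across libraries. Genes that share reads with close copies, such as the AKR1C family, heat shock HSPA1 genes and mitochondrial pseudogenes, have uncertain counts. The files do not mark strands, so sense and antisense reads could not be separated.

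There were 9 comparisons: each treated group with untreated cells, imatinib 1 µM and 10 µM with rapamycin 1 µM, the doses of each drug, and both imatinib doses with both rapamycin doses. An F test asked for any difference among the 5 groups. The comparisons, the 38 gene lists and the rule for naming genes were fixed before the data were examined. The lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether genes move on balance to a single side and does not compare them with other genes. A list needed 5 tested members.

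Genes were named by rule. Against untreated cells and between drugs these were the 6 highest and 6 lowest log2 fold changes among protein-coding genes that passed the threshold, had a mean of at least 1 CPM in the higher group and had groups that did not overlap. For the dose comparisons 4 at each end were taken. Up to 4 members with the smallest adjusted p were named in each list that passed or had at least 3 members that passed. In addition, 17 genes were fixed, of which 16 were tested. KIT had a mean of 1.47 counts and was not tested. A readthrough gene at 0 in a group, which the rule picked, is not described. Some genes that the rule picks are not reported here.

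The alternatives, whose effects are given in the closing section, were DESeq2 1.42.0, limma-voom, edgeR with relative log expression factors or library size only, no filter, a filter of 1 CPM in 3 libraries, a replicate block, only the libraries compared, transcript sums with length offsets, and each library left out. Leaving out a library leaves 2 in its group, and the pooled dispersion then assumes like spread in all groups. Chosen after the data were seen were fits without FN1, without mitochondrial genes, and with a spline (4 degrees of freedom) of GC content and transcript length removed. GC content and length were known for 96.1% of tested genes. For transcript sums, 88.3% of transcripts matched a gene, holding 94.9% to 95.1% of counts.

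Recovery was tested on simulated data built from the counts, with 200 genes changed. With 3 libraries per group and a log2 change of 0.5, 1 or 2, recovery was 63.6%, 80.6% and 95.4% for rapamycin 1 µM (14019 genes). It was 59.1%, 82.1% and 97.0% for rapamycin 0.05 µM (14025 genes). For imatinib 1 µM it was 61.5%, 80.0% and 95.5% (14016 genes), and for imatinib 10 µM 64.2%, 83.3% and 92.3% (14011 genes). False calls were 1.25% to 6.06% of all calls. The simulated changes were far fewer than the 2088 to 7662 genes called against untreated cells, with rises and falls about equal. These percentages may therefore not carry over to the real comparisons. Overlaps between comparisons that share untreated libraries were set against 20 simulated sets without any effect. Group labels were also redistributed over the libraries, in all 10 splits of 3 and 3 or in 100 drawn splits. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.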

Results

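RNA was sequenced from UMB1949 cells, a human line grown from a renal angiomyolipoma, a kidney tumour of muscle-like cells, fat cells and vessels that arises in tuberous sclerosis. That disorder is caused by loss of TSC1 or TSC2, genes whose products restrain the growth kinase complex mTORC1. Cells were deprived of serum overnight and then kept for 24 h in complete medium alone, with rapamycin, an inhibitor of mTORC1, at 0.05 or 1 µM, or with imatinib, an inhibitor of the ABL, KIT and PDGF receptor kinases, at 1 or 10 µM. Each of the 5 groups had 3 libraries. The series set out to compare the RNA profiles of the drugs. The labels do not say whether libraries came from separate cultures, so p-values measure only the spread between these libraries. Control cells are described as given medium alone, and no drug vehicle is named. Anything besides the drugs that all treated cells shared thus cannot be separated from treatment in comparisons with untreated cells.

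Depth was 17419592 to 29978782 estimated counts per library. Group means (± SD, n = 3) were 22.8 ± 3.36 M counts in untreated cells, 21.4 ± 1.06 and 20.7 ± 2.02 M counts with rapamycin 0.05 and 1 µM, and 27.6 ± 2.09 and 22.6 ± 5.10 M counts with imatinib 1 and 10 µM. Replicates correlated across genes at 0.982 to 0.990 (Pearson, log2 CPM; genes are not independent replicates). Imatinib 10 µM replicate 2 was the shallowest library and the farthest from its group, with a median absolute log2 difference of 0.171 against 0.0840 to 0.121 in the others. In that library IL1RL1, an interleukin receptor gene, stood at 75.1 CPM against 317 and 322 in the others of its group, the collagenase gene MMP1 at 209 CPM against 558 and 665, and the heme oxygenase gene HMOX1 at 1783 CPM against 704 and 756. These 3 genes were picked after their values were seen. Transcripts of the mitochondrial genome made up 1.56 ± 0.174% of counts in untreated cells, 2.70 ± 0.311% and 2.58 ± 0.0752% with rapamycin 0.05 and 1 µM, and 2.72 ± 0.417% and 4.23 ± 0.524% with imatinib 1 and 10 µM.

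**Figure D1:**
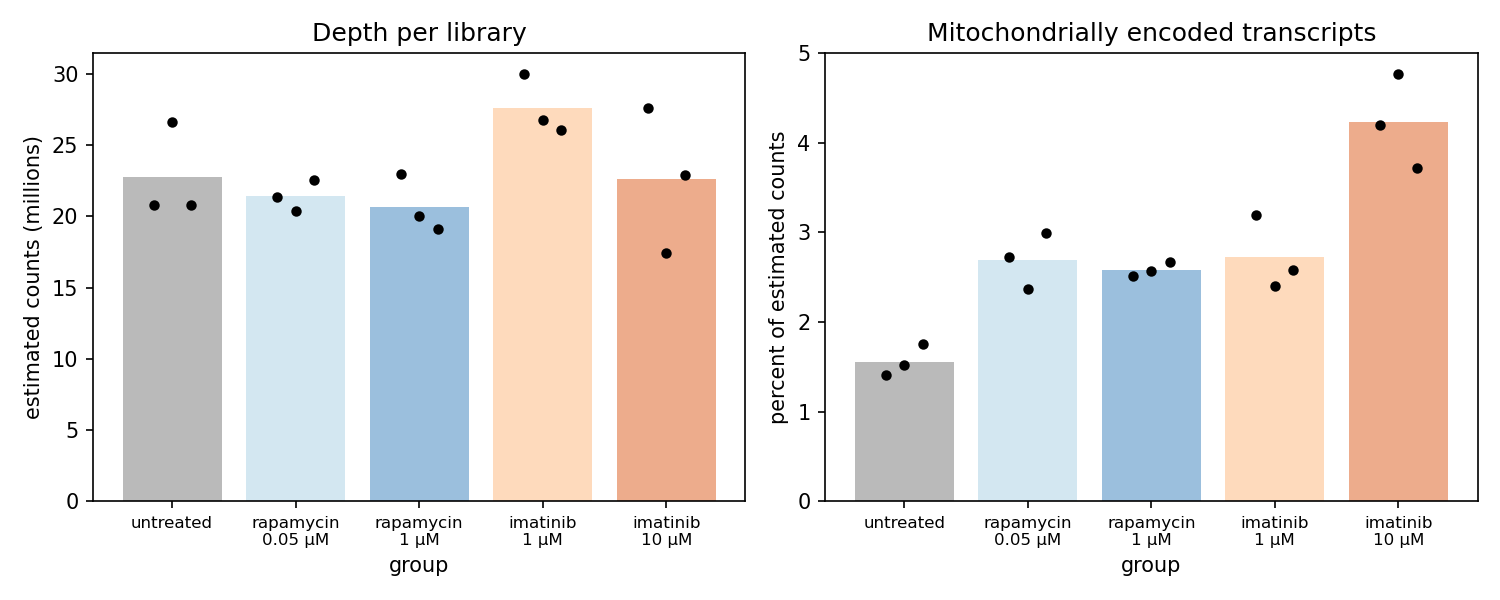
Depth in M estimated counts (left) and percent of counts from the mitochondrial genome (right) for the 5 groups; bars are means and points are the 3 libraries of each group. The mitochondrial share was lowest in untreated cells (mean 1.56%) and highest with imatinib 10 µM (mean 4.23%).

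Rapamycin 1 µM was compared with untreated cells to find which genes differed with the drug. Genes for building ribosomes and for protein folding fell, growth factor immediate early genes fell steeply, and many genes of smooth muscle, extracellular matrix and p53 rose. Those last 3 lists passed at the preset correlation only (adjusted p = 0.29, 0.29 and 0.11 with an estimated correlation). FOSB, which encodes an AP-1 transcription factor (chromosome 19, 45467995 to 45475179, GRCh38), fell from 1090 ± 58.1 to 11.2 ± 5.50 CPM, a log2 change of -6.61 ± 0.32 (SE, n = 3; adjusted p = 2.5e-08). RRP12, a ribosome assembly gene (chromosome 10, 97356358 to 97426076), fell from 211 ± 11.8 to 71.7 ± 2.47 CPM (-1.56 ± 0.05, adjusted p = 4.0e-14). TXNIP, whose product limits glucose uptake (chromosome 1, 145992435 to 145996579), rose from 91.4 ± 7.57 to 376 ± 12.8 CPM (2.04 ± 0.05, adjusted p = 4.0e-15). ACTA2, which encodes smooth muscle actin (chromosome 10, 88935074 to 88991339), rose from 2.45 ± 0.394 to 17.5 ± 0.775 CPM (2.84 ± 0.16, adjusted p = 5.4e-11).

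Of 14186 genes, 7662 passed the threshold with rapamycin 1 µM, 3732 higher and 3930 lower. Of these 903 were higher and 262 lower by at least 2-fold. The largest rises by rule included ADAMTS13 (4.02 ± 0.34), a protease that cleaves von Willebrand factor, ZMAT1 (4.02 ± 0.46), YPEL1 (3.93 ± 0.50) and ST6GALNAC2 (3.61 ± 0.34), all below 1 CPM in untreated cells. The largest falls after FOSB were NR4A1, NR4A3 and NR4A2, orphan nuclear receptor genes (-4.92 ± 0.25, -4.61 ± 0.44 and -4.13 ± 0.24), and the transcription factor gene OSR2 (-3.73 ± 0.12).

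Among 35 ribosome biogenesis genes tested, 34 fell and 1 rose with rapamycin 1 µM (median -0.69, adjusted p = 2.1e-04 with an estimated correlation), including NPM1 (-1.07 ± 0.05) and GNL3 (-0.96 ± 0.05). Ribosomal protein genes went apart: 32 of 74 fell, such as RPL24 (-0.39 ± 0.04), and 6 rose, such as RPL3 (0.28 ± 0.04). Of 15 heat shock genes 13 fell and 1 rose (median -0.75, adjusted p = 0.0075 with an estimated correlation), led by the mitochondrial chaperone genes HSPD1 (-1.14 ± 0.05) and HSPE1 (-1.05 ± 0.05). Of 30 immediate early and ERK feedback genes 20 fell and 3 rose (23 and 3 adjusted over the list alone; median -0.84, adjusted p = 0.038 with an estimated correlation). JUNB fell (-2.24 ± 0.07), and MYC, a growth-promoting transcription factor gene, went the other way (1.02 ± 0.07).

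Glycolysis genes fell in 15 of 21 cases and rose in 2 (adjusted p = 6.5e-08, but adjusted p = 0.16 with an estimated correlation), among them PFKM (-0.91 ± 0.06) and LDHA (-0.90 ± 0.06). Of 23 NRF2 target genes, which answer oxidative stress, 18 fell and 1 rose (adjusted p = 0.28 with an estimated correlation), among them AKR1C2 (-1.41 ± 0.07) and TKT (-0.92 ± 0.04). Of 23 cholesterol synthesis genes 15 fell and 2 rose (median -0.32, adjusted p = 0.61 with an estimated correlation). INSIG1, a feedback regulator gene of sterol synthesis, fell by 1.23 ± 0.08 (adjusted p = 1.2e-09). Nuclear respiratory chain genes fell in 20 of 35 cases and rose in 4 (adjusted p = 0.55 with an estimated correlation), as with ATP5F1B (-0.52 ± 0.04). Transcripts of the mitochondrial genome rose in 8 of 13 cases and fell in 0 (median 0.44, adjusted p = 0.66 with an estimated correlation), led by MT-CO1 (1.24 ± 0.14).

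Of 31 collagen and matrix genes 19 rose and 2 fell with rapamycin 1 µM (adjusted p = 0.29 with an estimated correlation), including the collagen crosslinking genes LOXL1 (1.13 ± 0.08) and LOX (0.92 ± 0.08). Smooth muscle genes rose in 7 of 15 cases and fell in 0 (adjusted p = 0.29 with an estimated correlation), including TAGLN (1.90 ± 0.16) and MYOCD (1.71 ± 0.26). Of 26 p53 target genes 16 rose and 3 fell (adjusted p = 0.11 with an estimated correlation). TP53INP1 rose (1.54 ± 0.11), as did CDKN1A, a cell cycle inhibitor gene (0.61 ± 0.05), and PLK3 fell (-2.22 ± 0.09). Mitosis genes rose in 21 of 40 cases and fell in 5 (adjusted p = 0.55 with an estimated correlation), among them CENPF (0.63 ± 0.06), and the proliferation marker gene MKI67 rose (0.47 ± 0.07). FOXO targets were mixed, with 9 higher and 5 lower of 20 (adjusted p = 0.039, and 0.16 with an estimated correlation); without rapamycin 0.05 µM replicate 3 or imatinib 1 µM replicate 1 adjusted p was 0.0527 or 0.0521. TSC2 rose slightly (0.21 ± 0.05, adjusted p = 0.0027), as did MTOR (0.18 ± 0.05), while TSC1 did not pass (-0.02 ± 0.06).

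Rapamycin 0.05 µM was compared with untreated cells as the lower dose. FOSB stood at 6.51 ± 0.839 CPM (-7.39 ± 0.34, adjusted p = 1.8e-08), RRP12 at 75.2 ± 1.61 CPM (-1.49 ± 0.05, adjusted p = 5.7e-14), TXNIP at 356 ± 5.05 CPM (1.96 ± 0.05, adjusted p = 8.1e-15) and ACTA2 at 15.9 ± 2.33 CPM (2.70 ± 0.16, adjusted p = 1.2e-10). In all, 7532 genes passed, 3719 higher and 3813 lower, and 865 and 255 of them by at least 2-fold. Ribosome biogenesis genes fell in 34 of 35 cases (adjusted p = 2.5e-04 with an estimated correlation), heat shock genes in 12 of 15 with 2 risen (adjusted p = 0.0091 with an estimated correlation), and immediate early genes in 20 of 30 with 3 risen (20 and 4 adjusted over the list alone; adjusted p = 0.043 with an estimated correlation). The angiogenic factor gene VEGFA fell (-1.72 ± 0.11) and VEGFC rose (0.88 ± 0.06). YPEL1 (3.86 ± 0.50), ZMAT1 (3.78 ± 0.46) and P2RY6 (3.65 ± 0.68) rose most. Lists lost with an estimated correlation were glycolysis (15 of 21 fell, adjusted p = 0.13), NRF2 targets (17 of 23 fell, adjusted p = 0.22), matrix (19 of 31 rose, adjusted p = 0.13), smooth muscle (9 of 15 rose, adjusted p = 0.13), p53 targets (17 of 26 rose, adjusted p = 0.065) and FOXO targets (10 of 20 rose, adjusted p = 0.13). Also lost were mitosis (23 of 40 rose, adjusted p = 0.52), mitochondrial genome transcripts (11 of 13 rose, adjusted p = 0.63), respiratory chain genes (22 of 35 fell, adjusted p = 0.47) and ribosomal proteins (37 of 74 fell, adjusted p = 0.81). The ribosomal protein call was also lost without untreated replicate 3 (adjusted p = 0.0511) or rapamycin 0.05 µM replicate 3 (adjusted p = 0.0755).

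The rapamycin doses were set against each other for an effect of dose. ACTA2 (0.14 ± 0.13, adjusted p = 0.93), VEGFA (0.10 ± 0.11, adjusted p = 0.95) and the cyclin gene CCND1 (-0.18 ± 0.05, adjusted p = 0.59) did not pass. By edgeR 0 genes passed and 852 had an unadjusted p under 0.05. DESeq2 called 6 genes, limma-voom 0, and edgeR on only the libraries compared 22. Without imatinib 10 µM replicate 2 there were 6, and without rapamycin 1 µM replicate 2 or 3 there was 1. Among 12789 genes of at least 1 CPM, 95% of the fitted log2 differences lay between -0.34 and 0.37. The list with the smallest camera p was cholesterol synthesis, with a median of -0.16 and 5 of 23 lower when adjusted over the list alone (adjusted p = 2.7e-10, but adjusted p = 0.26 with an estimated correlation). NF-kB cytokine genes had a median of -0.19, with 3 lower adjusted over the list alone (adjusted p = 0.26 with an estimated correlation). In all, 12 lists passed at the preset correlation and 0 with an estimated correlation. Without rapamycin 0.05 µM replicate 1 the 12 became 6, and without rapamycin 1 µM replicate 1 they became 7.

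**Figure D2:**
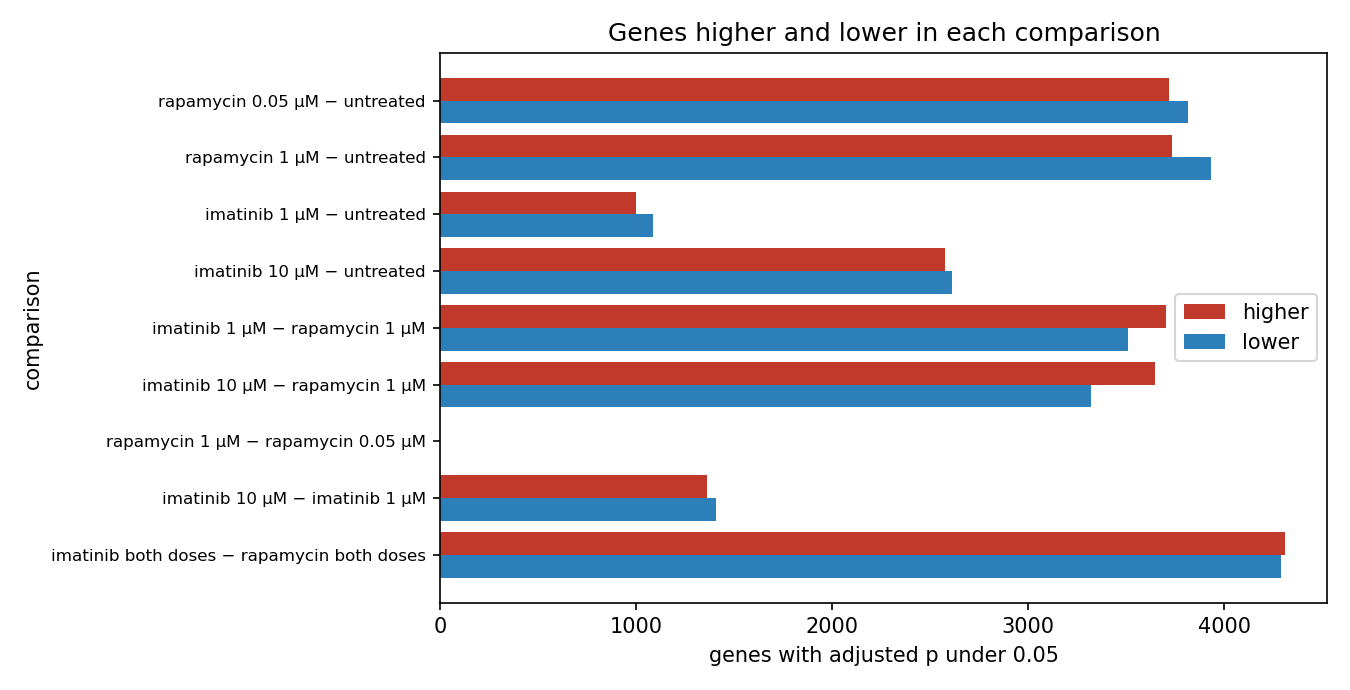
Number of genes with an adjusted p under 0.05 (horizontal axis), higher in red and lower in blue, for the 9 comparisons. Bars start at 0; rapamycin 1 µM against untreated cells has 3732 higher and 3930 lower, and the rapamycin doses differ in 0 genes.

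Imatinib 1 µM was compared with untreated cells to find which genes differed at the lower dose. Cholesterol and fatty acid synthesis genes rose and immediate early, NF-kB and TGF-beta response genes fell. MSMO1, a sterol synthesis enzyme gene, rose from 34.3 ± 2.80 to 78.2 ± 2.56 CPM (1.19 ± 0.08, adjusted p = 5.2e-09). SCD, a fatty acid desaturase gene (chromosome 10, 100347233 to 100364826), rose from 49.7 ± 5.54 to 189 ± 6.53 CPM (1.92 ± 0.16, adjusted p = 7.3e-06). FOSB fell to 5.08 ± 2.07 CPM (-7.75 ± 0.34, adjusted p = 8.5e-08). CA9, a carbonic anhydrase gene switched on in hypoxia, rose from 1.88 ± 0.577 to 6.02 ± 1.56 CPM (1.65 ± 0.30, adjusted p = 0.0013).

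With imatinib 1 µM 2088 genes passed, 1001 higher and 1087 lower (1383 and 760 with library size only), and 71 and 123 of them by at least 2-fold (46 rises with DESeq2). Without imatinib 10 µM replicate 2, which enters through the pooled dispersion, 2782 passed, and without imatinib 1 µM replicate 2 1396 passed. The largest rises also held NRROS (1.85 ± 0.32), MMP1 (1.83 ± 0.38) and the lipid droplet gene PLIN4 (1.72 ± 0.32), and the largest falls NR4A2 (-5.82 ± 0.28), NR4A1 (-5.09 ± 0.25) and ATF3 (-4.65 ± 0.30).

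Of 23 cholesterol synthesis genes 21 rose and 0 fell with imatinib 1 µM (22 adjusted over the list alone; median 0.74, adjusted p = 0.0031 with an estimated correlation), such as FDFT1 (1.03 ± 0.09) and IDI1 (0.74 ± 0.07). Of 16 fatty acid synthesis genes 9 rose (median 0.27, adjusted p = 0.024 with an estimated correlation), such as FASN (0.86 ± 0.06) and FADS2 (1.08 ± 0.08). Lysosome genes rose in 20 of 36 cases and fell in 1 (23 and 1 adjusted over the list alone; adjusted p = 0.056 with an estimated correlation), led by TPP1 (0.67 ± 0.05). Mitochondrial genome transcripts rose in 12 of 13 cases (median 0.66, adjusted p = 0.087 with an estimated correlation). Interferon response genes rose in 9 of 29 cases and fell in 1 (adjusted p = 0.42 with an estimated correlation), such as IFIT3 (0.59 ± 0.08), a call lost without untreated replicate 3 (adjusted p = 0.135 for the list).

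Immediate early genes fell in 14 of 30 cases and rose in 1 with imatinib 1 µM (adjusted p = 0.0031 with an estimated correlation), including JUNB (-2.83 ± 0.07) and the phosphatase gene DUSP1 (-1.55 ± 0.06). NF-kB cytokine genes fell in 12 of 23 cases (14 adjusted over the list alone; median -0.49, adjusted p = 0.0090 with an estimated correlation), including NFKBIA (-1.20 ± 0.05) and IL11 (-3.34 ± 0.28). TGF-beta and YAP targets fell in 10 of 21 cases and rose in 1 (adjusted p = 0.0058 with an estimated correlation), including SMAD7 (-2.49 ± 0.14) and SKIL (-1.31 ± 0.08). Of 26 p53 targets 12 fell and 2 rose (adjusted p = 0.0038 with an estimated correlation), and of 20 FOXO targets 8 fell (adjusted p = 0.0031 with an estimated correlation). PLK3 (-2.62 ± 0.09), BTG2 (-0.97 ± 0.09), TRIB1 (-1.32 ± 0.08) and KLF2 (-3.09 ± 0.24) led those lists, and these are also genes that growth factors or stress switch on quickly. Apoptosis genes fell in 10 of 34 cases and rose in 1 (adjusted p = 0.021 with an estimated correlation), including MCL1, which protects cells (-1.30 ± 0.07), and BBC3, which kills them (-1.34 ± 0.15). Of 14 PDGF axis and imatinib target genes 5 fell (7 adjusted over the list alone; adjusted p = 0.024 with an estimated correlation), including ABL1 (-0.25 ± 0.06) and PDGFRB (-0.48 ± 0.12; without untreated replicate 1 -0.40, adjusted p = 0.0519). Ribosomal protein genes fell slightly in 38 of 74 cases (63 adjusted over the list alone; median -0.15, adjusted p = 0.39 with an estimated correlation). Collagen and matrix genes fell in 10 of 31 cases and rose in 2 (14 and 3 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation), such as COL5A2 (-0.59 ± 0.04).

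Imatinib 10 µM was compared with untreated cells as the higher dose. Cholesterol, fatty acid and lysosome genes and mitochondrial transcripts rose, and many collagen and cell cycle genes and the PDGF receptor genes fell. The collagen, DNA replication and mitosis lists passed at the preset correlation only (adjusted p = 0.16, 0.18 and 0.19 with an estimated correlation). MSMO1 reached 106 ± 8.99 CPM (1.63 ± 0.08, adjusted p = 3.7e-11), SCD 242 ± 59.8 CPM (2.28 ± 0.16, adjusted p = 6.8e-07) and CA9 14.7 ± 5.74 CPM (2.95 ± 0.29, adjusted p = 1.2e-06). COL5A2, a fibrillar collagen gene (chromosome 2, 189031898 to 189225312), fell by 1.02 ± 0.04 on the log2 scale (adjusted p = 2.3e-12), and COL3A1 fell by 1.16 ± 0.08. PDGFRA, a PDGF receptor gene, fell by 0.70 ± 0.11 (adjusted p = 4.8e-05) and PDGFRB by 0.49 ± 0.12 (adjusted p = 0.0029). FOSB stood at 7.01 ± 2.63 CPM (-7.33 ± 0.34, adjusted p = 6.1e-08).

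With imatinib 10 µM 5185 genes passed, 2575 higher and 2610 lower (3471 and 1831 with library size only), and 378 and 182 of them by at least 2-fold. The largest rises after CA9 were BEST1 (2.94 ± 0.45), VLDLR (2.71 ± 0.56), ZNF114 (2.51 ± 0.36) and SLC7A8 (2.47 ± 0.34). Cholesterol synthesis genes rose in 22 of 23 cases (median 1.03, adjusted p = 0.00996 with an estimated correlation), including IDI1 (1.15 ± 0.07) and MVD (1.15 ± 0.08). Fatty acid synthesis genes rose in 10 of 16 cases and fell in 1 (adjusted p = 0.035 with an estimated correlation). Lysosome genes rose in 30 of 36 cases and fell in 0 (30 and 1 adjusted over the list alone; median 0.39, adjusted p = 0.030 with an estimated correlation), including TPP1 (1.00 ± 0.05) and CTSB (0.68 ± 0.05). Mitochondrial genome transcripts rose in 12 of 13 cases (median 1.21, adjusted p = 0.035 with an estimated correlation), and MT-CO1 went from 3479 to 11480 CPM (1.72 ± 0.14). NRF2 targets rose in 12 of 23 cases and fell in 4 (adjusted p = 0.19 with an estimated correlation), led by AKR1C1 (58.7 to 166 CPM, adjusted p = 1.7e-12). Hypoxia genes rose in 12 of 20 cases and fell in 2 (adjusted p = 0.098 with an estimated correlation), led by NDRG1 (1.55 ± 0.09).

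Immediate early genes fell in 17 of 30 cases and rose in 2 with imatinib 10 µM (17 and 4 adjusted over the list alone; adjusted p = 0.030 with an estimated correlation). Ribosome biogenesis genes fell in 23 of 35 cases (24 adjusted over the list alone; median -0.22, adjusted p = 0.030 with an estimated correlation), including RRP12 (-0.62 ± 0.05). TGF-beta and YAP targets fell in 10 of 21 cases and rose in 3 (adjusted p = 0.035 with an estimated correlation), including AMOTL2 (-0.88 ± 0.06). PDGF axis genes fell in 9 of 14 cases (adjusted p = 0.033 with an estimated correlation), and PDGFC was among them (-0.74 ± 0.08). FOXO targets fell in 8 of 20 cases and rose in 3 (adjusted p = 0.035 with an estimated correlation), with TXNIP lower (-0.45 ± 0.06). Lost with an estimated correlation were collagens (16 of 31 fell, adjusted p = 0.16), DNA replication (25 of 42 fell, adjusted p = 0.18), mitosis (25 of 40 fell, adjusted p = 0.19), heat shock (10 of 15 fell, adjusted p = 0.052) and ribosomal protein genes (36 of 74 fell, adjusted p = 0.43). So were NF-kB genes (12 of 23 fell, adjusted p = 0.196), smooth muscle genes (6 of 15 fell, adjusted p = 0.196) and fibroblast genes (7 of 11 fell, adjusted p = 0.073). MCM2 (-0.36 ± 0.04) and KIF23 (-0.45 ± 0.05) stood for the cell cycle lists. MKI67 fell slightly (-0.21, adjusted p = 0.019) and lost its call with library size only (-0.15, adjusted p = 0.121), without untreated replicate 2 (-0.16, adjusted p = 0.113) and without imatinib 10 µM replicate 2 (-0.13, adjusted p = 0.0790). TSC1 rose (0.46 ± 0.06, adjusted p = 1.5e-05), and ACTA2 did not pass (0.19, adjusted p = 0.43).

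**Figure D3:**
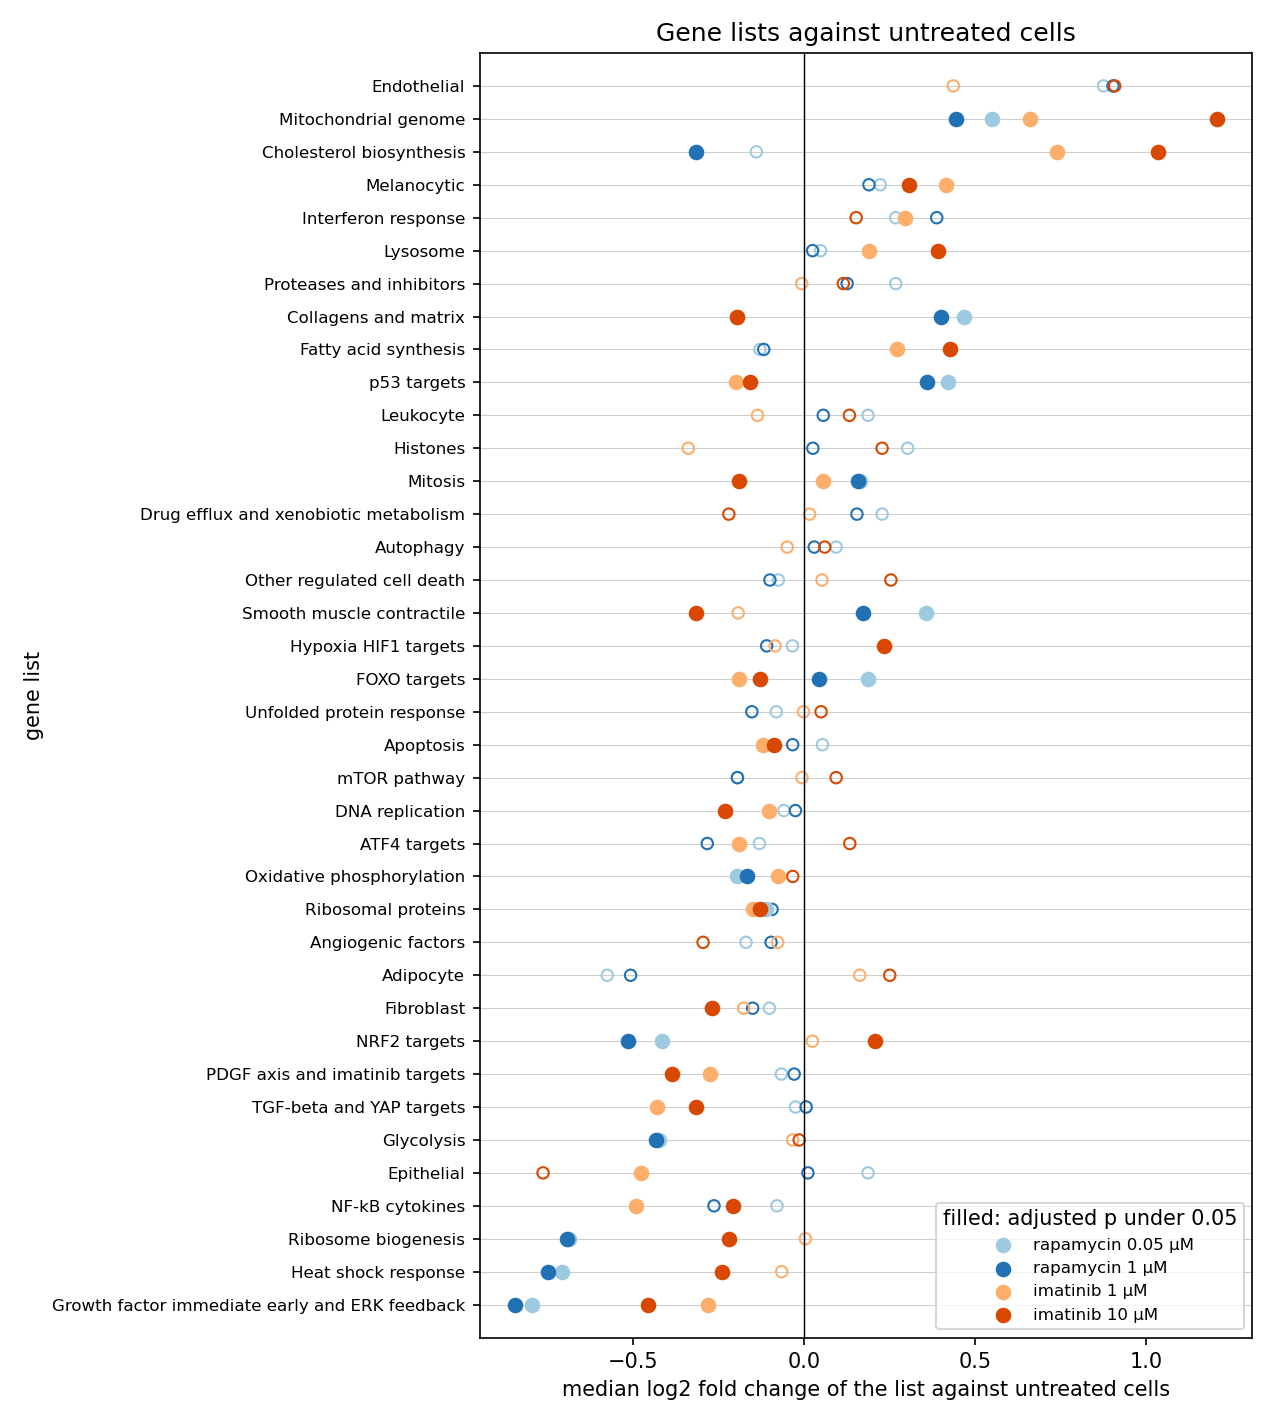
Median log2 fold change against untreated cells (horizontal axis) of the tested members of 38 gene lists, in 4 colours for the treated groups; filled points passed camera at the preset correlation (adjusted p under 0.05) and open points did not. Cholesterol synthesis genes had medians of 0.74 and 1.03 with imatinib 1 and 10 µM and of -0.32 with rapamycin 1 µM.

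The imatinib doses were compared for an effect of dose. NDRG1, a stress and hypoxia gene, was higher at 10 µM (1.17 ± 0.08, adjusted p = 5.5e-08), as were ENO2 (1.07 ± 0.07) and AKR1C1 (0.82 ± 0.06), and MKI67 was lower (-0.58 ± 0.07, adjusted p = 4.1e-05). Against untreated cells MKI67 fell by less with imatinib 10 µM (-0.21, adjusted p = 0.019). Its difference between doses therefore does not measure a fall from untreated cells. In all, 2769 genes differed, 1360 higher and 1409 lower (1645 and 1043 with library size only), and 104 and 23 by at least 2-fold. Those last counts became 55 and 12 without imatinib 1 µM replicate 3, 55 and 21 without imatinib 10 µM replicate 2, and 134 and 39 without imatinib 10 µM replicate 1, and the falls were 14 without imatinib 1 µM replicate 2. Without imatinib 1 µM replicate 3 1463 genes passed and without its replicate 2 1494. Hypoxia genes were higher in 13 of 20 cases and lower in 1 (15 and 1 adjusted over the list alone; adjusted p = 0.019 with an estimated correlation). Mitosis genes were lower in 26 of 40 cases (30 adjusted over the list alone; adjusted p = 0.028 with an estimated correlation), such as ANLN (-0.49 ± 0.06), and ribosome biogenesis genes in 20 of 35 (27 adjusted over the list alone; adjusted p = 0.0068 with an estimated correlation), such as NCL (-0.45 ± 0.06). ATF4 targets, which answer amino acid and other stress, were higher in 23 of 37 cases (27, with 2 lower, adjusted over the list alone; adjusted p = 0.17 with an estimated correlation), among them SLC1A4 (1.01 ± 0.10) and PHGDH (0.63 ± 0.08). Cholesterol synthesis genes were higher in 15 of 23 cases (adjusted p = 0.16 with an estimated correlation), lysosome genes in 22 of 36 (adjusted p = 0.15 with an estimated correlation) and NF-kB genes in 9 of 23 with 1 lower (adjusted p = 0.17 with an estimated correlation).

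Imatinib at each dose was compared with rapamycin 1 µM, the question the series poses. Cholesterol, ribosome and heat shock genes were higher with imatinib and matrix, smooth muscle, p53 and FOXO genes were lower. At 1 µM the matrix and smooth muscle lists were lost (adjusted p = 0.071 and 0.090 with an estimated correlation). At 10 µM, INSIG1 was higher by 2.16 ± 0.08 (adjusted p = 1.2e-12), CA9 by 4.63 ± 0.35 (adjusted p = 1.8e-08) and AKR1C2 by 2.18 ± 0.07. TXNIP was lower (-2.49 ± 0.06, adjusted p = 1.4e-16), as were COL5A2 (-1.28 ± 0.04, adjusted p = 4.2e-14) and ACTA2 (-2.65 ± 0.16). At 1 µM, INSIG1 was higher (1.64 ± 0.08), and TXNIP (94.1 ± 1.33 against 376 ± 12.8 CPM, adjusted p = 5.2e-15), BBC3 (-2.28 ± 0.15) and ACTA2 (-2.81 ± 0.15) were lower. At 10 µM 6970 genes differed, 3648 higher and 3322 lower (328 and 569 by at least 2-fold), and at 1 µM 7210, 3702 and 3508 (237 and 729).

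At 10 and 1 µM of imatinib against rapamycin 1 µM, cholesterol synthesis genes were higher in 21 of 23 cases (adjusted p = 0.0043 and 0.0103 with an estimated correlation) and ribosome biogenesis genes in 34 of 35 (adjusted p = 0.0038 and 1.2e-04 with an estimated correlation). Heat shock genes were higher in 11 of 15 cases at both doses (adjusted p = 0.040 and 0.0097 with an estimated correlation). FOXO targets were lower in 12 and 11 of 20 cases (adjusted p = 0.0043 and 0.0018 with an estimated correlation) and p53 targets in 17 and 20 of 26 (adjusted p = 0.0069 and 0.0018 with an estimated correlation), as with MDM2 (-1.10 ± 0.06 and -1.12 ± 0.06). Collagen and matrix genes were lower in 25 and 24 of 31 cases (adjusted p = 0.026 and 0.071 with an estimated correlation) and smooth muscle genes in 11 and 10 of 15 (adjusted p = 0.037 and 0.090 with an estimated correlation). NRF2 targets were higher in 19 and 17 of 23 cases (adjusted p = 0.026 and 0.12 with an estimated correlation) and glycolysis genes in 17 and 16 of 21 (adjusted p = 0.038 and 0.105 with an estimated correlation). At 10 µM mitosis genes were lower in 31 of 40 cases (adjusted p = 0.052 with an estimated correlation), such as CENPF (-0.95 ± 0.06).

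Both imatinib doses were also compared with both rapamycin doses (6 against 6 libraries). TXNIP was lower (-2.21 ± 0.04, adjusted p = 1.5e-18), as were COL5A2 (-1.10 ± 0.03, adjusted p = 1.0e-15), TAGLN (-2.95 ± 0.12) and ACTA2 (-2.66 ± 0.11). IL1RL1 (3.06 ± 0.36, adjusted p = 2.4e-05), PLIN4 (3.08 ± 0.26), AKR1C2 (1.97 ± 0.05, adjusted p = 6.2e-16) and VEGFA (1.15 ± 0.08) were higher. In all, 8601 genes differed, 4311 higher and 4290 lower, with 263 and 611 by at least 2-fold. Cholesterol synthesis genes were higher in 21 of 23 cases (22 adjusted over the list alone; median 1.01, adjusted p = 0.0058 with an estimated correlation), ribosome biogenesis genes in 34 of 35 (median 0.64, adjusted p = 6.6e-04 with an estimated correlation) and fatty acid synthesis genes in 15 of 16 (adjusted p = 0.047 with an estimated correlation). Collagen and matrix genes were lower in 24 of 31 cases (median -0.75, adjusted p = 0.022 with an estimated correlation) and p53 targets in 20 of 26 (adjusted p = 0.0030 with an estimated correlation). Smooth muscle genes were lower in 11 of 15 cases (adjusted p = 0.036 with an estimated correlation), and NRF2 targets were higher in 19 of 23 (adjusted p = 0.042 with an estimated correlation). In none of the 9 comparisons did a list that passed camera have a median, mean and test that differed in sign. TSC1 was higher (0.36) and TSC2 lower (-0.21) with imatinib than with rapamycin. Against untreated cells TSC2 did not pass with imatinib 10 µM (-0.028, adjusted p = 0.72). Among all 5 groups, 9848 genes differed by the F test.

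**Figure D4:**
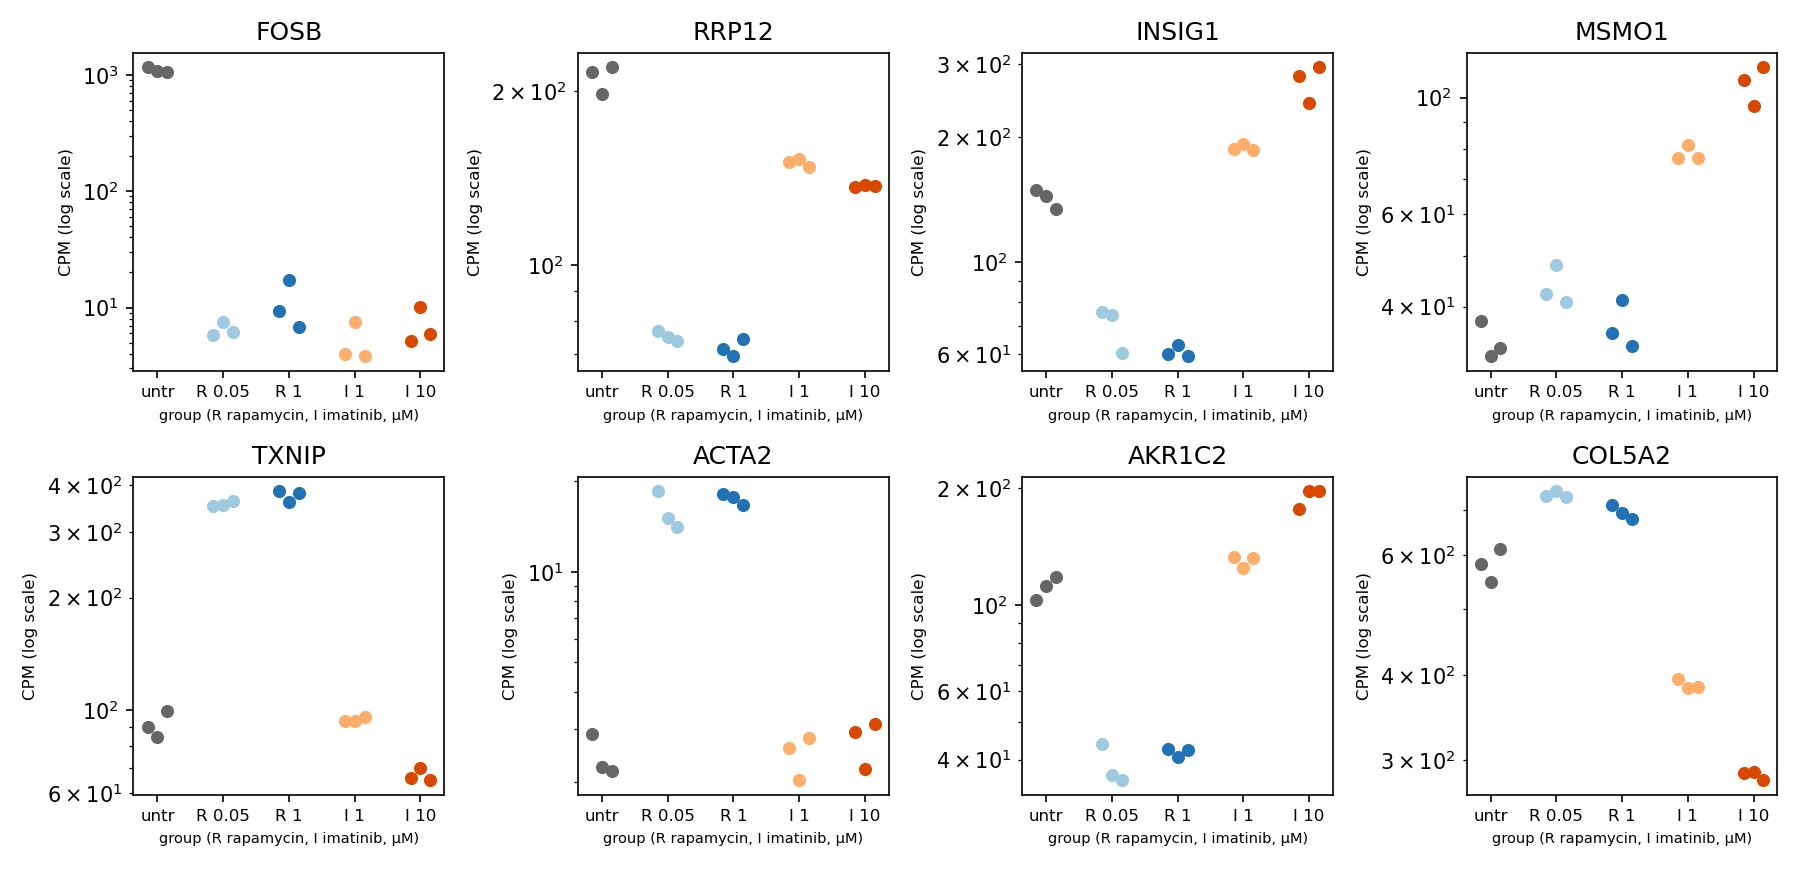
CPM on a log axis for FOSB, RRP12, INSIG1, MSMO1, TXNIP, ACTA2, AKR1C2 and COL5A2 in each of the 15 libraries, by group; each point is a library. FOSB lies near 1090 CPM in untreated cells and at group means of 5.08 to 11.2 CPM in the treated groups, and ACTA2 is lower with imatinib 1 and 10 µM than with rapamycin 1 µM (log2 -2.81 and -2.65).

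Calls against untreated cells were set side by side to ask which genes the treatments shared. In all 4 treated groups 53 genes fell by at least 2-fold, among them FOSB, FOS, NR4A1, NR4A2, NR4A3, ATF3, JUNB, KLF4 (-3.31 with rapamycin 1 µM and -2.80 with imatinib 10 µM), IL11 and SNAI1, a regulator of cell migration. Another 30 rose by at least 2-fold in all 4, among them MT-CO1, the follistatin gene FST (2.47 and 1.24) and CTSK, which encodes cathepsin K (1.83 and 2.14). Without imatinib 1 µM replicate 1 that number was 16. Most of the 30, CTSK included (0.449 CPM), lay below 1 CPM in untreated cells. FAM167B, SNX32, KREMEN2 and MTCO3P12 lay there below the floor of 3 counts. Several were pseudogenes, and MTCO1P12 and MTCO3P12 may share reads with mitochondrial transcripts. Of the 53 lower genes 51 were annotated as coding. These 53 also held the pseudogene PPIAP22, and both SIK1 and SIK1B, which may share reads. The rapamycin doses shared 3185 higher and 3469 lower genes where independence gives 978 and 1056, and 0 were opposite. The imatinib doses shared 803 and 844 (182 and 200 by independence), and 10 were opposite. Rapamycin 1 µM and imatinib 10 µM shared 1351 and 1569 (677 and 723), and 668 were opposite. Rapamycin 1 µM and imatinib 1 µM shared 514 and 658 (263 and 301), and 355 were opposite. The 1172 genes of that last pair were 772 without untreated replicate 1.

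All these comparisons used the same 3 untreated libraries, which alone gave mean correlations across genes of 0.493 to 0.517 over 20 simulated sets without effects, with at most 1 gene shared. The observed correlations were 0.867 between rapamycin doses, 0.704 between imatinib doses, 0.528 for rapamycin 1 µM with imatinib 10 µM and 0.455 with imatinib 1 µM. The highest simulated correlations for these pairs were 0.540, 0.586, 0.551 and 0.569, and the values between the drugs did not exceed them. This comparison of correlations cannot decide whether the drugs shared effects, since the simulations changed no gene and the real data changed many. Observed covariances were 0.439, 0.203, 0.221 and 0.161, against simulated means of 0.0493, 0.0495, 0.0484 and 0.0494 and a highest of 0.0608, 0.0606, 0.0550 and 0.0596. The 3 controls cannot be split, so part of the excess, FOSB and NR4A1 included, may come from them.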

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

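The tests of a lone untreated library, of the state of the untreated cultures, of ERK signalling, of nuclear respiratory chain genes, of GC content and length, of low counts and of transcripts that keep introns or lack a coding sequence were chosen only after the result was seen. The rules behind the side-by-side counts were also set then.

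The drugs moved some genes in opposite directions. The rule that picked them also required the difference between imatinib 10 µM and rapamycin 1 µM to pass the threshold. There were 668 opposite genes, against 2920 that passed in the same direction with both. No number expected by independence was computed for opposite genes, so 668 is not shown to be more than that. With rapamycin higher and imatinib lower than in untreated cells there were 288 genes. The largest differences were in TAGLN, a smooth muscle gene (1.90 and -0.85), SULF1 (1.77 and -0.95), PAPPA, a protease gene that frees insulin-like growth factor (1.48 and -1.17), TXNIP (2.04 and -0.45) and TRIM22 (1.66 and -0.69). With rapamycin lower and imatinib higher there were 380 genes, among them HMOX1 (-1.89 and 1.03), TM4SF19 (-1.48 and 0.83), FAM180A (-1.70 and 0.49) and AKR1C2 (-1.41 and 0.78). The 380, out of 14186 tested genes, held 14 of 23 cholesterol synthesis genes, 10 of 36 lysosome genes and 8 of 23 NRF2 targets. The 288, out of 14186, held 12 of 40 mitosis genes, 8 of 31 collagen and matrix genes and 6 of 26 p53 targets. HMOX1 with imatinib 10 µM rests on a spread of 704 to 1783 CPM.

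The 53 genes that fell by at least 2-fold in every treated group had a median log2 change of -2.05. They held 5 of the 30 immediate early and ERK feedback genes (FOS, FOSB, JUNB, KLF6 and DUSP5) and 3 of 23 NF-kB cytokine genes, and the orphan receptor genes NR4A1, NR4A2 and NR4A3. A lone untreated library is argued against, since at least 51 of them stayed whichever of the 3 was left out. Lower ERK signalling with imatinib cannot be told apart from other causes: 1 of 10 ERK feedback genes was lower at both doses (DUSP6, -0.96 and -0.76). DUSP4 and ETV4 passed as higher at 10 µM only (0.78 and 0.39, adjusted p = 0.014 and 6.3e-04). The 10 left out DUSP5, an ERK phosphatase gene that was lower at both doses (-1.02 and -1.02). For either drug the test could not argue against lower ERK signalling. It also required that no other immediate early gene was lower at both doses, and FOS, FOSB, JUNB, KLF6 and DUSP5 already were. With rapamycin 3 of 10 were lower at both doses (DUSP6, SPRY2 and SPRY4) while ETV4 and ETV5 were higher, so lower ERK signalling there cannot be told apart from other causes by genes that moved both ways. An activated state of the untreated cultures at harvest cannot be told apart from a drug effect either, because all comparisons used those cultures: 31 of the 53 differed between the drugs, which bears on part of the change and leaves a common part open. The same holds for a vehicle or handling that only treated cells received, since controls are described as given medium alone.

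Transcripts of the mitochondrial genome had median log2 changes of 0.55, 0.44, 0.66 and 1.21 with rapamycin 0.05 and 1 µM and imatinib 1 and 10 µM. Imatinib 10 µM replicate 2 alone is argued against, since 13 of 13 transcripts were higher without it (median 1.13). A general rise of respiratory chain transcripts is argued against, since 3 of 35 nuclear-encoded genes rose with imatinib 10 µM and ATP5F1B fell (-0.28). The make-up of the RNA differed in other ways, as seen afterwards. Transcripts that keep introns held 3.78 to 3.83% of counts of matched transcripts with imatinib 10 µM against 3.21 to 3.59% in untreated cells, and reached 3.82% with rapamycin 1 µM. Coding transcripts held 89.5 to 89.8% against 90.2 to 90.6%, and long non-coding ones 0.155 to 0.161% against 0.115 to 0.127%. With rapamycin 1 µM coding transcripts held 89.9 to 90.3% and long non-coding ones 0.151 to 0.173%, though mitochondrial transcripts rose less there. These shares do not separate RNA quality from an effect of the drug, and the number of mitochondria was not measured, so technical and biological causes remain open.

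Rises of at least 2-fold outnumbered falls with rapamycin 1 µM, 903 to 262. Removing trends on GC content and transcript length left a ratio of 3.13 against 3.45, which argues against those trends. Of the 903 risen genes 752 had a coding transcript that could be followed. Among these, 628 (83.5%, interval 80.7 to 86.1, genes taken as independent) kept 2-fold over coding transcripts alone. That was 89.2% of the 704 that were 2-fold higher over all their transcripts. This argues against counts assigned to transcripts that keep introns or lack a coding sequence as the main source. It cannot exclude more of such RNA, since reads that transcripts of a gene share are divided between them by estimation. The other 151 risen genes could not be followed. Without genes of that kind the ratio stayed at 3.16 (752 rises and 238 falls), which argues against them as the source of the uneven numbers. Few counts per gene remain open. Among genes above the median CPM the ratio was 0.611 (66 rises and 108 falls), and below it there were 837 rises and 154 falls, so 92.7% of rises but 58.8% of falls lay there. What made the low-count genes uneven was not tested.

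Other splits of the libraries were counted for each comparison. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split alone, 1 of 10, gave as many genes for rapamycin 0.05 µM (7532 genes, highest other 0), rapamycin 1 µM (7662, highest other 1), imatinib 1 µM (2088, highest other 1) and imatinib 10 µM (5185, highest other 0) against untreated cells. The same held for imatinib 1 µM (7210, highest other 0) and 10 µM (6970, highest other 0) against rapamycin 1 µM and between imatinib doses (2769, highest other 0). Between rapamycin doses all 10 of 10 gave 0. For both doses of imatinib against both of rapamycin 1 of 100 splits reached the real 8601 (highest other 3450). For any difference among the 5 groups 1 of 100 reached 9848 (highest other 2493). For that pair of results this argues against a chance assignment of single libraries to groups. It does not cover chance differences between cultures, since the labels do not say whether libraries came from separate cultures.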

How the results depend on the processing

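Fits without FN1, without mitochondrial genes, with GC and length offsets, and every setting applied to the side-by-side counts were chosen after the data were seen. Of 33577 values of named genes under the alternatives, 33098 kept their side of the threshold, 436 lost their call, 40 gained one and 3 reversed. Of 6498 values of lists 6166 kept their side, 156 lost their call, 175 gained one and 1 reversed. Among those that kept their side, 48 values of genes and 58 of lists, none of them past the threshold, changed sign. Total counts of genes past the threshold, of shared genes and of lists stayed within 1.5 times under every setting except those given here, and the cause was not tested unless stated.

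Between rapamycin doses 0 genes became 3 with no filter, 1 with GC and length offsets, 6 with DESeq2 and 22 with only the libraries compared. Between imatinib doses only the libraries compared gave 1253 genes, 1227 of them shared with the 2769, from a fit with fewer libraries. Rises of at least 2-fold between imatinib doses went from 104 to 56 with only the libraries compared, and over left-out libraries from 55 to 134, with falls of 12 to 39 against 23. With imatinib 1 µM the 71 such rises became 46 with DESeq2. The 30 genes higher in all treated groups became 19 with DESeq2 and 15 with only the libraries compared. Lists that passed with an estimated correlation numbered 3 and 3 for rapamycin 0.05 and 1 µM, 9 and 9 for imatinib 1 and 10 µM, 5 and 10 for imatinib 1 and 10 µM against rapamycin 1 µM, 0 between rapamycin doses, 3 between imatinib doses and 10 for both doses of each drug. That setting widens each test by the correlation within a list. By fry, which does not compare a list with other genes, they numbered 27 and 30 for the rapamycin doses, 31 and 33 against rapamycin 1 µM, 0 between rapamycin doses, 25 between imatinib doses and 34 for both doses.

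Leaving out each library gave 6616 to 8032 genes for rapamycin 0.05 µM, 6791 to 8125 for rapamycin 1 µM, 1396 (without imatinib 1 µM replicate 2) to 2782 for imatinib 1 µM and 4231 to 5179 for imatinib 10 µM. It gave 6363 to 7702 and 6206 to 6985 against rapamycin 1 µM, 0 to 6 between rapamycin doses, 1463 (without imatinib 1 µM replicate 3) to 3002 between imatinib doses, 8195 to 8829 for both doses and 9391 to 10029 for any difference. Shared genes were 5876 to 7096 for the rapamycin doses, 1118 to 2153 for the imatinib doses, 2316 to 2925 for rapamycin 1 µM with imatinib 10 µM, and 772 (without untreated replicate 1) to 1541 with imatinib 1 µM. Genes lower in all groups were 53 to 61, genes higher in all 16 (without imatinib 1 µM replicate 1) to 36, and opposite genes 215 to 336 and 283 to 411. Lists ranged over 12 to 14 and 12 to 16 for the rapamycin doses, 17 to 23 and 21 to 25 for the imatinib doses, 11 to 12 and 20 to 21 against rapamycin 1 µM, 6 (without rapamycin 0.05 µM replicate 1) to 13 between rapamycin doses, 15 to 19 between imatinib doses and 15 to 18 for both.

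With transcript sums and length offsets, where the transcript map is incomplete, the kinase gene DDR1 reversed to -0.91 (adjusted p = 0.23) with rapamycin 1 µM and to 0.045 (adjusted p = 0.96) for imatinib 10 µM against rapamycin 1 µM, and the apoptosis gene BCL2L11 reversed to 0.21 (adjusted p = 0.47) for both doses. For ribosomal protein genes between imatinib doses, the signed logarithm of the adjusted p (positive for higher) was -1.32 without imatinib 10 µM replicate 2 and at most 0.497 (without replicate 3), against 0.027 with all libraries.

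Replicate numbers did not pair the libraries: 3 of 15 correlated best with their own number across groups. A replicate block gave 7352, 7511, 1848 and 4973 genes against untreated cells. With that block 14 lists passed for rapamycin 1 µM, 8 of them lower, against 13 and 7 without it. With library size only, NCOA4, ATP5F1A, NDUFB5, SDHD, HSP90AB1, LUM and PRRX1 lost their call with imatinib 1 µM, as did AQP1, ABCC1, DDR1, CCND1 and MKI67 with imatinib 10 µM. At this depth genes near 1 CPM rest on few counts, and the tested recovery of small changes was below that of large ones.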

Other observations

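Some gene groups did not pass as lists while members moved. With rapamycin 1 µM 16 of 36 lysosome genes rose and 13 fell (adjusted p = 0.20), with CTSF (1.67 ± 0.09) and GAA (1.06 ± 0.08), which encodes a glycogen-digesting enzyme, among the risen. Autophagy genes rose in 11 of 30 cases and fell in 6 (adjusted p = 0.48): ULK2 rose (1.06 ± 0.10) and the cargo receptor gene SQSTM1 fell (-0.97 ± 0.08). SQSTM1 rose with imatinib 10 µM (0.90 ± 0.08), and the difference between the drugs was 1.88 ± 0.08. Unfolded protein response genes fell in 11 of 23 cases and rose in 1 (adjusted p = 0.052), led by the chaperone gene HSPA5 (-0.92 ± 0.06). Interferon response genes rose in 14 of 29 cases and fell in 3 (adjusted p = 0.070), such as ISG15 (0.60 ± 0.07). NF-kB cytokine genes fell in 12 of 23 cases and rose in 6 (adjusted p = 0.052), with IL11 lower (-2.94 ± 0.28). ATF4 targets fell in 16 of 37 cases and rose in 5 (adjusted p = 0.087). Leaving out a library brought these lists past the threshold in some cases: without untreated replicate 2 adjusted p was 0.0399 for the unfolded protein response, 0.0155 for interferon and 0.0360 for ATF4 targets, and without untreated replicate 3 it was 0.00661 for NF-kB genes. Without rapamycin 1 µM replicate 2 it was 0.0312 for the unfolded protein response and for interferon, and without imatinib 10 µM replicate 2 it was 0.0214 for ATF4 targets and 0.0208 for NF-kB genes. The unfolded protein response and NF-kB lists also passed without several other libraries, at 0.0323 to 0.0493.

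Of 13 genes in the pigment cell list 5 passed the expression filter, and PMEL and CTSK were below 1 CPM in untreated cells. PMEL, a pigment cell gene, rose with rapamycin 1 µM from 0.665 to 1.73 CPM (1.38 ± 0.36, adjusted p = 0.0034), and CTSK rose from 0.449 to 1.61 CPM (1.83 ± 0.32). GPNMB, a gene of pigment cells and lysosomes, fell with rapamycin 1 µM (-0.20 ± 0.06, adjusted p = 0.0082), a call lost without rapamycin 1 µM replicate 3 (-0.16, adjusted p = 0.0502). MITF, a pigment cell regulator gene, fell (-0.35 ± 0.12, adjusted p = 0.023), a call lost without untreated replicate 1 or 2 (adjusted p = 0.0843 and 0.0831) or rapamycin 1 µM replicate 2 or 3 (adjusted p = 0.0821 and 0.119). GPNMB rose with imatinib 1 and 10 µM (0.73 ± 0.06 and 0.97 ± 0.06). Of 7 endothelial genes 3 rose with rapamycin 1 µM (adjusted p = 0.26), among them the VEGF receptor gene KDR (1.14 ± 0.19). Of 8 adipocyte genes 4 fell and 1 rose (adjusted p = 0.34), including PPARG (-0.74 ± 0.12). mTOR pathway genes were mixed with rapamycin 1 µM, 14 lower and 7 higher of 30 (adjusted p = 0.40), with RRAGC (-0.75 ± 0.08) and AKT1S1 (-0.69 ± 0.08) among the lower. With imatinib 10 µM 11 rose and 6 fell (adjusted p = 0.18), with DEPTOR, an mTOR inhibitor gene, lower (-1.48 ± 0.17) and FLCN higher (0.61 ± 0.08).

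FN1, the fibronectin gene, was picked after its values were seen, as the gene with the most counts in 13 of the libraries. It made up 3.53% to 4.06% of counts with rapamycin and 1.39% to 1.78% in untreated cells. It rose with rapamycin 1 µM (1.22 ± 0.10, adjusted p = 2.7e-07) and fell with imatinib 10 µM (-0.48 ± 0.09, adjusted p = 0.0015).

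The first 4 principal components of 500 genes held 26.8%, 13.6%, 8.76% and 7.03% of the variance.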
